A study of Homo sapiens with 3 samples.

How the data were processed

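The series holds 3 samples of KYSE510, an established human esophageal squamous cell carcinoma line. Per the labels, the cells received lentivirus carrying a scrambled short hairpin RNA (control), hairpin 1 (sh1) or hairpin 2 (sh2) for 24 h, followed by 48 h under 4 µM puromycin. Total RNA was extracted with Trizol and sequenced as BGISEQ-500 libraries, per the labels' protocols. Each sample came with 3 numbered gene tables, which gives 9 tables in 3 groups. The labels do not say whether the 3 tables of a sample are separate cultures, separate libraries or repeat runs, so p-values measure only the spread between these libraries, which may be technical. Before they were averaged, the tables of each sample were compared by a chi-square over genes with a mean of at least 20 counts. The chi-square per gene lay between 1.41 and 2.43, above sampling noise, which does not show that the tables are separate cultures. The 3 tables were treated as 3 libraries (n = 3 per group), although there is 1 sample per group, and every SE, adjusted p and count of calls rests on that choice. With the tables of each sample summed, 2 hairpin samples stand against 1 control, and the only spread left is the difference between the hairpins. A test of their mean then counts what the hairpins do differently as error, so it could not decide. No call therefore has the support of a test between samples.

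The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the build hg19, without saying what each was used for. Per the file headers, each table gives an expected count, a TPM and an FPKM value for each of 19266 genes under Entrez gene identifiers. The deposited expected counts are estimates that need not be whole: 70.0% to 70.4% of the values per library lay within 1e-06 of a whole number. The FPKM values deposited by the authors were used only in 2 alternatives, on a log2 scale with a pseudocount of 1 or 0.1 and for genes with a mean of at least 1 FPKM, so that those fold changes understate the change of low genes. A table of FPKM values for the whole series holds the same values and was not used. Gene symbols came from a RefSeq table of assembly GRCh38.p14, used for names alone, which gave a symbol to 19206 of the 19266 identifiers. No coordinates are printed because that assembly is not the submitters' build. Whether the counting used strand is not given in the sources used here, so genes that overlap, lie antisense to each other or have near-identical copies are uncertain.

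Expected counts were rounded to whole numbers and analysed in R 4.3.3. The total of expected counts per library was 14660821 to 16092417, 15498 to 15807 genes were above 0, and the 10 most abundant genes took 3.41% to 3.8% of a library. A floor of 3 counts corresponds to 0.186 to 0.205 CPM (counts scaled to a common library size), for counting error only. With edgeR 4.0.16, genes were kept by filterByExpr (13580 of them), libraries were scaled by TMM, and all 9 libraries entered 1 quasi-likelihood fit with group as the only term. The contrasts were sh1 against control, sh2 against control, sh1 against sh2, and the mean of the hairpins against control. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. What edgeR terms the biological coefficient of variation was 2.33%. Here it measures the spread between the tables of a sample, which may be technical. Levels are CPM as mean ± SD, and fold changes are log2 values ± SE, all with n = 3 libraries per group. The SE was derived from the fit, as the absolute log2 fold change divided by the square root of the quasi-likelihood F. For genes with few counts, such as MAFA with sh2 (12 counts), it can lie below counting error alone and understates their uncertainty.

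On counts simulated for the comparison of sh1 with control (13580 genes, 50 changed at each size), the same test recovered 20% of genes changed 1.1-fold, 72% at 1.25-fold, 88% at 1.5-fold and 92% at 2-fold. Of its calls, 2.86% were false, and a simulated sh2 group without changes gave 0 calls. The simulated spread was that between the tables of a sample, and few genes were changed. These rates therefore do not cover differences between single cultures, which the real contrasts may hold. In 20 further simulations, 2 unchanged groups were compared with the same control libraries. They gave a mean of 0 genes called the same way in both, a correlation of log2 fold changes of 0.5, a covariance of 0.0111 and the same sign for 66.8% of genes. These simulations, too, held no spread between cultures.

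Before the data were examined, 39 gene lists were fixed. Lists with at least 5 tested members (37 of them) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The Benjamini-Hochberg adjustment ran over lists and the 3 pairwise contrasts. An estimated correlation and fry, which asks whether the genes of a list move on balance one way, were the alternatives. The correlation was estimated from the deviations of libraries from their group mean. It therefore does not allow for genes of a list that move together between single cultures. Genes named were chosen by a rule fixed at the same time, among genes with a mean of at least 1 CPM. It takes the 12 rises and 12 falls shared by both hairpins, at least 2-fold in each, with every hairpin library beyond every control library, that rank first by the smaller change. It adds the 5 genes each way that the hairpins moved in opposite directions and that were also called between the hairpins, ranked likewise. It then takes the 8 rises and 8 falls of greatest size per hairpin without overlap between the libraries of the groups. Up to 4 members per list, those with the smallest p for the mean of the hairpins, and ACTB with GAPDH complete it. For lists described between the hairpins, the rule asked for the smallest p of that contrast instead, which was not applied. The limit of 1 CPM, on the mean over the 9 libraries, was not applied to list members by the script, and CSF1R is the named gene below it. Genes outside this rule are marked as chosen after their values were seen.

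The alternatives fixed at the same time were the size factors of DESeq2, library size alone or upper quartile factors in place of TMM, DESeq2 1.42.0, limma-voom, the FPKM values, no filter or a filter of 10 counts, fits of only the groups compared, the file number as a block, other thresholds, omission of each library, and the files of each sample summed. The targeted transcript, TCONS_02256997, was matched by identifier alone. As 0 identifiers in the tables hold that name, its level was not analysed here, and the labels could not be checked by the knockdown itself.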

Results

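The transcriptome of KYSE510 cells was measured after infection with a scrambled hairpin or with 1 of 2 hairpins against the transcript TCONS_02256997, to screen for potential targets of that transcript. There was 1 sample per group with 3 numbered tables each, treated as 3 libraries; the labels do not say whether these are separate cultures, separate libraries or repeat runs. Total expected counts were 15012961 to 15414591 in the control libraries, 14660821 to 14770512 with sh1 and 15759270 to 16092417 with sh2. The targeted transcript was not analysed here. The first 2 principal components of log2 CPM carried 46.1% and 37.9% of the variance and set the 3 groups apart.

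The first question was which genes both hairpins moved the same way against control. The falls of greatest size included CCN2, CHAC1, IL1A and CXCL8. CCN2 (Entrez gene 1490), a matricellular protein and YAP target, went from 262 ± 2.98 CPM in control to 8.82 ± 1.42 with sh1 and 25.5 ± 1.58 with sh2 (SD, n = 3). CHAC1 (79094), a glutathione-degrading enzyme induced by ATF4, went from 64.9 ± 0.848 CPM to 3.98 ± 0.103 and 6.1 ± 0.275. The cytokine genes IL1A (3552) and CXCL8 (3576) had log2 fold changes of -3.87 ± 0.052 and -3.05 ± 0.04 with sh1, and -3.24 ± 0.047 and -3.3 ± 0.04 with sh2. Of the 12 shared rises of greatest size, MT2A (4502), a metallothionein, had the highest control level and went from 48.6 ± 5.51 CPM to 361 ± 34.7 with sh1 and 294 ± 11.7 with sh2.

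Among other shared falls, TCIM changed by -3.34 ± 0.041 and -3.09 ± 0.039, and the immediate early transcription factor EGR1 (1958) by -3.29 ± 0.05 and -3.06 ± 0.048, for sh1 and sh2 in that order. FOSB, a FOS family factor, changed by -2.84 ± 0.094 and -2.52 ± 0.088, and GLI1, a Hedgehog pathway factor, by -2.52 ± 0.319 and -2.7 ± 0.321. TUBB2B, a beta-tubulin, changed by -3.15 ± 0.191 and -4.62 ± 0.231, MAFA by -2.92 ± 0.29 and -3.88 ± 0.328, and FGL1 by -2.93 ± 0.151 and -2.92 ± 0.148. The hormone gene FGF21 (26291) had 351 counts over the control libraries, 27 with sh2 and 2 with sh1. Its control level was 13.6 times that with sh2 (95% interval 9.21 to 21, exact Clopper-Pearson, counting error only) and 170 times that with sh1 (46.7 to 1410). The largest adjusted p for these falls was 3.73e-08 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, GLI1 with sh1).

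Among the shared rises, CEACAM6 (4680), a cell adhesion molecule, rose by 3.43 ± 0.114 with sh1 and 3.07 ± 0.119 with sh2 on the log2 scale, and VTCN1, an immune checkpoint ligand, by 2.61 ± 0.152 and 2.64 ± 0.15. IVL (3713), a precursor of the cornified envelope of squamous cells, rose by 2.36 ± 0.147 and 3.97 ± 0.114, more with sh2. AGR2, a disulfide isomerase of secretory cells, rose by 2.05 ± 0.063 and 2.58 ± 0.058, and SMPD1, the acid sphingomyelinase, by 2.17 ± 0.364 and 3.53 ± 0.296. The smooth muscle genes ACTG2 (3.44 ± 0.25 and 3.38 ± 0.251) and MYL9 (2.51 ± 0.464 and 3.4 ± 0.4) rose from control levels of 0.44 ± 0.156 and 0.176 ± 0.139 CPM. For MYL9 that level rests on 8 counts over the control libraries and lies below the floor of 3 counts per library. The size of its rise is therefore uncertain. SDCBP2 rose by 2.61 ± 0.187 and 2.2 ± 0.195 and NEK10 by 2.27 ± 0.367 and 2.68 ± 0.341. ALPP rose by 2.26 ± 0.096 and 2.61 ± 0.091 and its near-identical neighbour ALPG by 2.22 ± 0.284 and 2.68 ± 0.264, with the split of reads between them uncertain; the summed counts of the family rose by 2.19 and 2.54. The largest adjusted p for these rises was 1.98e-05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, MYL9 with sh1).

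**Figure D1:**
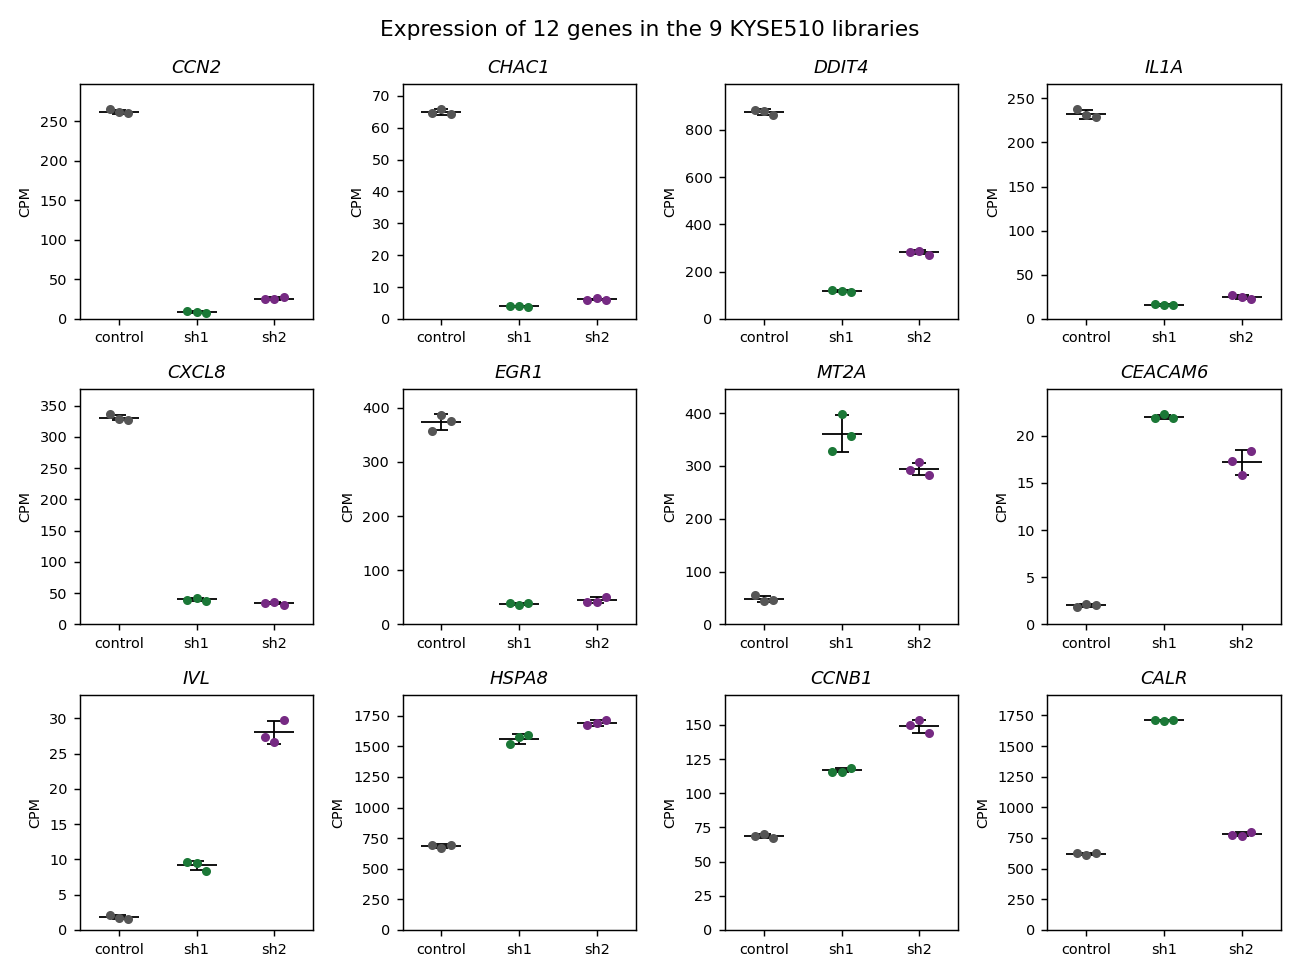
Expression of 12 named genes (CPM, linear axes from 0) in the control, sh1 and sh2 groups; points are the 3 libraries of a group, the wide line is their mean and the bar its SD. CCN2, CHAC1, DDIT4, IL1A, CXCL8 and EGR1 lie lower in every library of both hairpins than in control, and the other 6 genes lie higher, with CALR at 1710 CPM with sh1 against 781 with sh2.

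Genes of the integrated stress response, the program run by the factor ATF4 under amino acid or protein-folding stress, fell as a group. All 29 measured members fell with each hairpin, 21 of them at least 2-fold with sh1 and 16 with sh2, and the median log2 changes were -1.35 and -1.11 (camera adjusted p = 5.73e-19 for both, and 0.0117 for both with an estimated correlation). DDIT4, an inhibitor of mTORC1, went from 877 ± 12.4 CPM to 119 ± 3.99 with sh1 and 282 ± 8.64 with sh2. STC2, a secreted glycoprotein, changed by -2.66 ± 0.038 and -2.45 ± 0.037, and the cystine transporter gene SLC7A11 by -2.06 ± 0.036 and -2.39 ± 0.037.

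NF-kB and inflammatory cytokine genes fell for 21 of 24 members with each hairpin, while 3 rose with sh1 and 2 with sh2. Their median changes were -1.29 and -1.14 (camera adjusted p = 1.91e-09 and 1.04e-09, and 0.0156 for both with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, went from 1800 ± 30.3 CPM to 572 ± 4.2 and 714 ± 22.2, and TNFAIP2 from 2010 ± 16.1 to 585 ± 12.2 and 1030 ± 16.6. YAP and TEAD targets fell for 17 of 23 members with sh1 and 18 with sh2, or 17 and 19 when adjusted over the list alone. Their medians were -0.42 and -0.82 (camera adjusted p = 3.85e-05 and 2.46e-06, and 0.0246 and 0.017 with an estimated correlation). AMOTL2 changed by -1.99 ± 0.034 and -1.73 ± 0.033, AJUBA by -1.5 ± 0.039 and -1.45 ± 0.038, and the tissue factor gene F3 by -2.72 ± 0.035 and -0.93 ± 0.029. The YAP1 gene itself changed by -1.34 ± 0.029 and -0.77 ± 0.028.

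Immediate early and AP-1 genes, which respond to growth factor signals, fell for 26 of 30 members with each hairpin, with medians of -1.63 and -0.78 (camera adjusted p = 2.08e-11 and 1.34e-09). With an estimated correlation the adjusted p was 0.0448 for sh1 and 0.0556 for sh2, so that the second call was lost. PHLDA1 changed by -3.13 ± 0.041 and -2.16 ± 0.036, the ligand gene EREG by -3.54 ± 0.063 and -1.66 ± 0.047, and JUNB by -1.66 ± 0.03 and -1.07 ± 0.029. TGF-beta and SMAD targets fell for 16 of 22 members with sh1 and 17 with sh2 (camera adjusted p = 0.0147 and 3.73e-05, and 0.0948 and 0.0246 with an estimated correlation). Among them ID1 changed by -1.11 ± 0.03 and -1.1 ± 0.03, and BHLHE40 by -1.87 ± 0.041 and -1.49 ± 0.039.

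Genes of the cell cycle moved the other way. Of 30 genes of the G1/S transition and DNA replication, 27 rose with sh1 and 28 with sh2, with medians of 0.69 and 0.6 (camera adjusted p = 7.5e-11 and 5.48e-11, and 0.0156 for both with an estimated correlation). E2F1, a factor that drives entry into S phase, rose by 1.56 ± 0.048 and 1.05 ± 0.05, RRM2, a subunit of ribonucleotide reductase, by 0.87 ± 0.032 and 0.84 ± 0.032, and PCNA by 0.79 ± 0.038 and 0.95 ± 0.037. Of 30 genes of G2/M and mitosis, 21 rose with sh1 and 28 with sh2, with medians of 0.31 and 0.79 (camera adjusted p = 0.000163 and 4.7e-13, and 0.0556 and 0.0145 with an estimated correlation). CCNB1, the mitotic cyclin B1, went from 68.7 ± 1.49 CPM to 117 ± 1.46 and 149 ± 4.7, and the kinesin gene KIF20A rose by 0.77 ± 0.038 and 1.29 ± 0.036. Heat shock chaperones rose for 13 of 20 members with sh1 and 15 with sh2 (camera adjusted p = 0.00814 and 2.41e-06, and 0.0825 and 0.017 with an estimated correlation). HSPA8, a constitutive cytosolic chaperone, went from 687 ± 14.3 CPM to 1560 ± 37.8 and 1690 ± 22.1, and HSP90AA1 from 1660 ± 11.9 to 3200 ± 12.8 and 3160 ± 63.5.

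**Figure D2:**
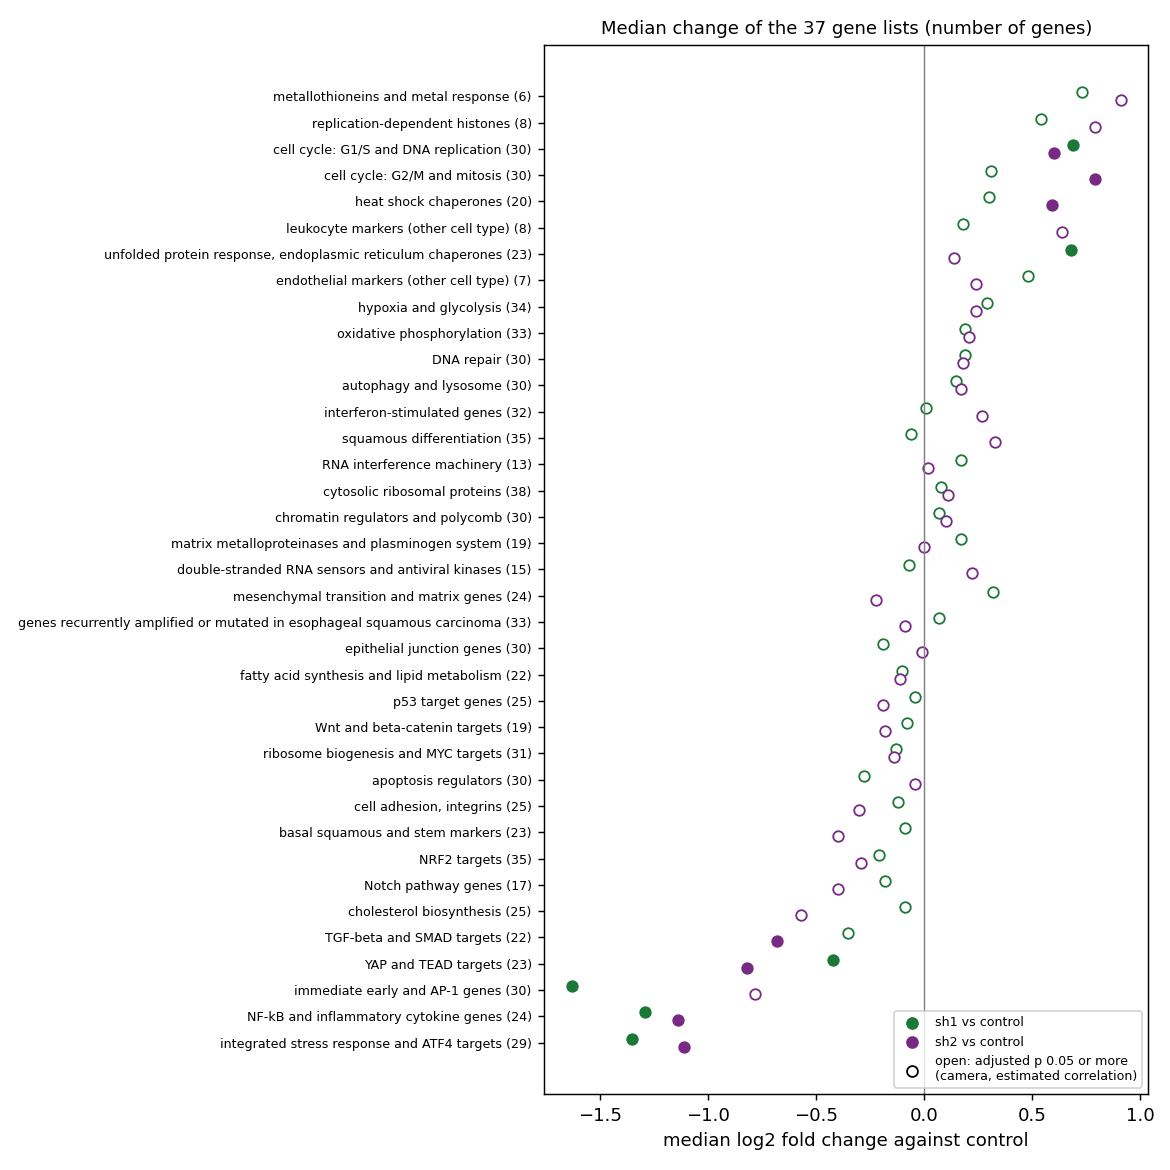
Median log2 fold change against control of the 37 tested gene lists (number of tested genes in brackets) for sh1 and sh2. Filled points passed camera with an estimated correlation at an adjusted p below 0.05, open points did not. That correlation was estimated between libraries of the same sample. The stress response list lies at -1.35 and -1.11 and the G1/S list at 0.69 and 0.6.

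Over all 13580 genes, sh1 called 9409 against control (4714 higher, 4695 lower) and sh2 9298 (4646 higher, 4652 lower). Both hairpins called 5374 genes the same way (2630 higher, 2744 lower), where independent lists of these sizes would share 1613 and 1608. At 2-fold or more, sh1 called 1242 genes, sh2 1053, and both called 432 the same way (191 higher, 241 lower, against 17 and 33 for independent lists). Across genes, which are not independent replicates, the log2 changes of the hairpins had a Pearson correlation of 0.544, a Spearman correlation of 0.472, the same sign for 66.3% of genes and a covariance of 0.211. Unchanged groups simulated against the same controls gave 0.5, 66.8% and 0.0111 for the correlation, the sign share and the covariance. The simulated groups held no spread between cultures, and both hairpins were set against 1 control sample. Splitting its libraries would not remove a state that they share. Part or all of the excess may therefore come from the shared control. The mean of both hairpins differed from control for 9431 genes (4610 higher, 4821 lower), 809 of them at 2-fold or more. With the files of each sample summed to 1 library, the only spread left is the difference between the hairpins. A test of that mean could then not decide, and none of these calls has the support of a test between samples.

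The second question was what each hairpin did against control on its own. With sh1, CYP1A1 (1543), a xenobiotic-metabolising enzyme induced through the aryl hydrocarbon receptor, rose by 4.12 ± 0.217, from 0.505 ± 0.203 CPM to 8.89 ± 0.549, and stood at 0.504 ± 0.133 CPM with sh2. CYP24A1 (1591), the vitamin D 24-hydroxylase, went from 120 ± 1.93 CPM to 2.44 ± 0.136 with sh1 and 30.4 ± 1.29 with sh2. The serpin genes SERPINB3 and SERPINB4, whose near-identical sequences leave the split of reads uncertain, changed by -4.89 ± 0.048 and -4.44 ± 0.051 with sh1 and by -2.24 ± 0.034 and -2.27 ± 0.039 with sh2. CCN3, a paralog of CCN2, rose by 3.69 ± 0.076 with sh1 and 1.76 ± 0.1 with sh2. CEACAM5 rose by 3.21 ± 0.13 and 1.56 ± 0.162, and SNPH by 3.17 ± 0.228 and 1.67 ± 0.278. GPR55 rose by 3.05 ± 0.299 and 1.69 ± 0.36, and GPR15LG changed by -3.55 ± 0.21 and -1.88 ± 0.161. S100A7, the squamous protein psoriasin, rose by 3.49 ± 0.135 with sh1 and by 0.68 ± 0.201 with sh2; the second call was lost without sh2 library 2 (0.48, adjusted p = 0.0562, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

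With sh2, CALCR (799), the calcitonin receptor gene, rose by 3.58 ± 0.334, from 0.308 ± 0.103 to 3.77 ± 0.996 CPM, and had a change of -1.38 ± 0.734 with sh1 that did not pass. ATP6V1B1, a subunit of the vacuolar proton pump, rose by 2.94 ± 0.14 with sh2 and 1.69 ± 0.169 with sh1. The phosphate transporter gene SLC34A2 changed by -3.42 ± 0.197 and -1.44 ± 0.15, and the factor gene KLF15 by -3.25 ± 0.362 and -2.22 ± 0.316, in that order. The readthrough gene RNF103-CHMP3, which shares exons with its neighbours, had 5.82 ± 5.53 CPM with sh2 against 0.369 ± 0.639 in control, with 12.2 CPM in sh2 library 2 and 2.44 and 2.81 in the others. Its change with sh2 was 3.94 ± 0.739 (adjusted p = 2.51e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), for RNF103-CHMP3 without sh2 library 2 it was 2.79, and DESeq2 did not call it (adjusted p = 0.134). Its sum with RNF103 and CHMP3 changed by 0.33. The reference genes moved too: ACTB changed by -0.45 ± 0.024 and -0.16 ± 0.024, and GAPDH by 0.17 ± 0.024 and 0.46 ± 0.024, for sh1 and sh2.

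FSBP and SULT1A3, with the largest fitted falls with sh1 and sh2 respectively among the 13580 tested genes, were chosen after their values were seen. FSBP had 0 counts with sh1 and 3.19 ± 2.76 CPM in control, while its sum with the overlapping gene RAD54B changed by -0.11. SULT1A3 had 0 counts with sh2 and 5.46 ± 4.73 CPM in control, while its sum with the near-identical SULT1A4 changed by 0.21.

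The third question was where the hairpins differed from each other. They differed for 9477 genes (4647 higher with sh1, 4830 lower), 1124 of them at 2-fold or more. Both hairpins called 1723 genes in opposite directions, 856 higher with sh1 and lower with sh2 and 867 the other way, and 9 of these passed 2-fold with both. SPARC (6678), a matrix glycoprotein, stood at 285 ± 0.686 CPM in control, 380 ± 1.66 with sh1 and 49.2 ± 0.392 with sh2. FTH1 (2495), the ferritin heavy chain, stood at 5020 ± 34.8, 6190 ± 176 and 1330 ± 68.2 CPM, and DHCR7, the last enzyme of cholesterol synthesis, at 2250 ± 43, 2390 ± 15.9 and 730 ± 7.48. The lysosomal membrane gene LAMP1 went the other way, with 230 ± 5.45, 69.5 ± 1.32 and 291 ± 4.33 CPM, while TLN1, encoding talin, fell with both hairpins and more with sh1, with 262 ± 6.41, 93.2 ± 3.19 and 232 ± 3.9. The integrin gene ITGAV fell by 1.62 on the log2 scale with sh2 and had 0.04 ± 0.03 with sh1. All of these differed between the hairpins with an adjusted p of at most 6.09e-24 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, TLN1).

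Chaperones and folding enzymes of the endoplasmic reticulum rose for 17 of 23 members with sh1 (median 0.68, camera adjusted p = 3.89e-05, and 0.0469 with an estimated correlation). With sh2, 14 rose and 8 fell, the median was 0.14 and the mean -0.01, and the list was not called (camera adjusted p = 0.502). The difference between the hairpins passed, with 17 members higher with sh1 and 0 lower (camera adjusted p = 1.09e-06, and 0.0249 with an estimated correlation). CALR went from 622 ± 7.77 CPM to 1710 ± 3.88 with sh1 and 781 ± 17.5 with sh2, HSP90B1 from 1100 ± 10.5 to 2490 ± 19.6 and 1610 ± 52.5, while XBP1, a factor of the same response, changed by -1.03 ± 0.038 and -1.09 ± 0.038. The G2/M list was lower with sh1 than with sh2 for 23 of 30 members (camera adjusted p = 1.36e-06, and 0.0249 with an estimated correlation). Sensors of double-stranded RNA were lower with sh1 than with sh2 for 14 of 15 members (median -0.36, camera adjusted p = 0.000447, and 0.0486 with an estimated correlation). OAS1 stood at 268 ± 4.76 CPM in control, 226 ± 4.94 with sh1 and 470 ± 4.34 with sh2.

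Interferon-stimulated genes were not called with sh1 (13 rose and 13 fell of 32, camera adjusted p = 0.794). With sh2, 22 rose and 8 fell (camera adjusted p = 0.000289, and 0.0948 with an estimated correlation). RSAD2 rose by 0.56 ± 0.045 with sh1 and 1.4 ± 0.041 with sh2, while IFITM1 changed by -0.78 ± 0.031 and -1.07 ± 0.031. Cholesterol biosynthesis genes fell for 20 of 25 members with sh2 (median -0.57, camera adjusted p = 9.95e-07, and 0.0903 with an estimated correlation) and were not called with sh1 (camera adjusted p = 0.499). In camera, the difference between the hairpins passed only with the preset correlation (camera adjusted p = 1.37e-05, and 0.12 with an estimated correlation). The alternative fry called it too (fry adjusted p = 1.39e-07). Squalene epoxidase, SQLE, stood at 596 ± 10.5, 547 ± 10.8 and 330 ± 4.91 CPM in control, sh1 and sh2. Of the 37 lists, the preset correlation called 13 with sh1, 21 with sh2 and 10 between the hairpins, and the estimated correlation 6, 7 and 3. fry, which asks whether a list moves on balance one way, called 35, 35 and 28. Apart from the YAP list, the list counts given for these 3 questions were the same when adjusted over the list alone.

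**Figure D3:**
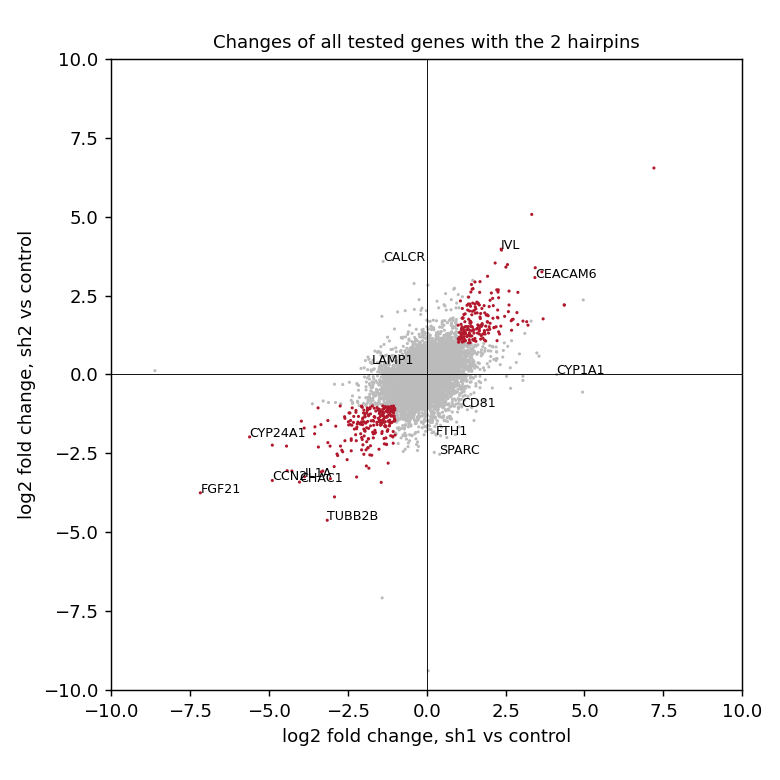
Log2 fold change against control of each tested gene with sh1 (horizontal axis) and sh2 (vertical axis); each point is a gene and red marks the 432 genes called the same way at 2-fold or more with both hairpins. Named points include FGF21, whose fitted value rests on 2 counts with sh1, and CYP1A1, which lies near 0 with sh2.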

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

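The tests of unequal knockdown and of equally distant cultures were chosen only after the result was seen; the GC and length tests and the other splits were chosen with the counts of calls and the genes of largest change in view but before their own outcomes, and the contrast between the hairpins and the omission of libraries were planned.

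The naming rule picked 10 genes that the hairpins moved in opposite directions. It required a call between the hairpins, so that their difference passed was fixed by the choice and adds no support. CD81, a tetraspanin, stood at 102 ± 8.96 CPM in control, 220 ± 6.53 with sh1 and 49.9 ± 1.43 with sh2, a difference between the hairpins of 2.14 ± 0.046 on the log2 scale. The same difference, sh1 minus sh2, was 2.1 ± 0.116 for the protease gene TMPRSS2, 2.05 ± 0.075 for GLB1L2, 2.04 ± 0.291 for PGLYRP4 and 2.42 ± 0.343 for EFNA2, an ephrin. In the other direction it was -3.26 ± 0.229 for UGT1A7, which shares exons with the other UGT1A genes, -2.24 ± 0.218 for FRMD3, -2.33 ± 0.1 for RELN (reelin), -2.3 ± 0.2 for LGALS9B, which has near-identical copies, and -1.81 ± 0.315 for TSGA10. The fall of EFNA2 with sh2 was -1.01 ± 0.421 and was no longer called without control library 1 (-0.51), sh2 library 2 (-0.84) or sh2 library 3 (-1.06). The fall of TSGA10 with sh1, -0.98 ± 0.359, was no longer called without control library 1 (-0.91), sh1 library 1 (-0.73) or sh1 library 3 (-0.81).

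Both hairpins moved 432 genes the same way by 2-fold or more, which leaves the control as the odd group. The odd group was sh1 for 428 genes and sh2 for 311, so the control stood apart for about as many genes as sh1 and for more than sh2. At any size the counts were 5374 (control), 5616 (sh1) and 5248 (sh2). With each of the others as baseline the correlation of changes was 0.53 (sh1) and 0.424 (sh2) against 0.544. These numbers stay open to 3 unrelated cultures at roughly similar distances, which could give them without a shared target. GC content and gene length as the whole cause are argued against: with both trends removed per library, 405 of the 432 genes (93.8%) were still called so. With 1 control sample, the state of that control culture and an effect of losing the targeted transcript cannot be told apart.

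The hairpins also differed from each other by 2-fold or more for 1124 genes. Of the 1120 with a GC and length value, 1030 (92%) were still called with both trends removed, which argues against these trends as the whole cause. A single target reduced to unequal degrees might give changes of unequal size in the same direction. Of 1398 genes called at 1.5-fold or more with both hairpins, 99 (7.08%) went opposite ways, between the bound of 5% set for that explanation and the bound of 10% set against it, so this test leaves it open. Off-target effects of a hairpin and differences between the cultures stay open and untested.

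Other splits of the libraries were compared with the real groups. With 1 sample per group, every other split mixes tables of different samples, so the spread between single samples is set against the spread within a sample. These counts therefore leave open whether chance differences between 3 cultures gave the calls. For each pairwise comparison only 10 splits of 6 libraries exist, too few for a share under 0.05. The real split alone (1 of 10) gave 9409, 9298 and 9477 calls, and the highest count of the other splits was 0 in each. For the called lists with the preset correlation, the real values were 13 (sh1) and 21 (sh2) against 9 and 15 for the highest other split, each reached by 1 of 10 splits. Between the hairpins the real value of 10 was reached by 2 of 10 splits. Of 100 splits into 3 groups of 3, drawn with a fixed seed and the real one included, 1 gave as many calls for the mean of the hairpins (9431, highest other 1186). The same held for calls in both the same way (5374, highest other 0) and opposite calls (1723, highest other 0).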

How the results depend on the processing

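All alternatives were planned before the data were examined. The counts of calls at any size stayed within 1.5 times their value for scaling, test, filter, FPKM and block alternatives. No called value of a named gene and no called list changed direction. At 2-fold or more, the calls came to 1242 (sh1), 1053 (sh2), 1124 (between hairpins), 809 (mean), 432 (both, same way) and 9 (opposite), and against a 1.2-fold threshold with glmTreat to 5460, 5257, 5310, 4667, 2468 and 340; both settings ask for a larger change by construction. With files summed to 1 library per sample, which leaves 2 hairpin samples against 1 control, edgeR called 0 genes for the mean (smallest adjusted p 0.113, 874 genes at an unadjusted p below 0.05 against 735 expected without any change), and 632 genes (336 higher, 296 lower) changed at least 2-fold the same way with both hairpins, without a test. Lists called were 6, 7 and 3 (sh1, sh2, between hairpins) with an estimated correlation and 35, 35 and 28 by fry; fry does not compare a list with other genes.

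Without each library in turn, calls ranged from 9003 to 9532 (sh1), 8867 to 9300 (sh2), 8983 to 9527 (between hairpins), 8868 to 9390 (mean), 5062 to 5291 (same way) and 1512 to 1714 (opposite), and lists from 12 to 13, 20 to 21 and 9 to 11. Of the 432 genes, 356 remained in every such fit. From FPKM the count of 432 became 199 with a pseudocount of 1 and 289 with 0.1 (199 and 284 of them shared with the 432); a pseudocount shrinks the fold changes of low genes by construction. File numbers did not pair the libraries: deviations of same-numbered libraries correlated between -0.07 and 0.09. With the number as a replicate block the counts were 9431, 9295, 9501, 9431, 5389 and 1727, and the lists 13, 21 and 11. Over all named genes, contrasts and alternatives, 8435 values kept direction and side, 209 no longer passed, 4 newly passed and 9 that had not passed changed sign. Of the 209, 160 came from the 2-fold threshold and 24 from glmTreat, which ask for a larger change by construction. Most named genes were picked for a large change or a small p, so this tally does not describe the other genes. The alternative of only the groups compared does not apply to the mean, which uses all 3. Depth limits genes near the floor, such as FGF21 with sh1.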

Other observations

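The test of culture density or slower growth below was chosen after the genes of largest change had been seen, and before any result of the gene lists was seen.

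Metabolic, redox and DNA repair genes moved in several lists that camera called with the preset correlation but not with an estimated one. The alternative fry called each of these lists with both hairpins, but it called 35 of the 37 lists with each hairpin, so this adds little. Hypoxia and glycolysis genes rose for 22 of 34 members with sh1 and 21 with sh2 (camera adjusted p = 0.0224 and 0.0023, and 0.129 and 0.0697 with an estimated correlation). Within that list the glucose transporter gene SLC2A1 rose by 0.77 ± 0.029 and 0.84 ± 0.029 and PGK1 by 0.48 ± 0.026 and 0.7 ± 0.026, while VEGFA changed by -1.84 ± 0.034 and -1.31 ± 0.033. NRF2 targets fell for 20 and 22 of 35 members (camera adjusted p = 0.0181 and 0.00354, and 0.273 and 0.186 with an estimated correlation), with GCLM, a subunit of the enzyme that starts glutathione synthesis, at -1.86 ± 0.039 and -1.11 ± 0.036. Oxidative phosphorylation genes rose for 20 and 23 of 33 (camera adjusted p = 0.0181 and 0.00268, and 0.641 and 0.527 with an estimated correlation). DNA repair genes rose for 15 and 19 of 30 (camera adjusted p = 0.0434 and 0.0147, and 0.186 and 0.125 with an estimated correlation), and the call of the list DNA repair, sh1 vs control, was lost without control library 2.

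Besides interferon-stimulated genes and cholesterol biosynthesis, which also differed between the hairpins with the preset correlation, the lists called with sh2 alone by that correlation were Notch pathway genes (12 of 17 fell, camera adjusted p = 0.00538, and 0.0748 with an estimated correlation), integrins and adhesion genes (19 of 25 fell, 0.000105 and 0.125), basal squamous markers (14 of 23 fell, 0.0143 and 0.293), replication-dependent histones (6 of 8 rose, 0.00538 and 0.122), leukocyte markers (6 of 8 rose, 0.0222 and 0.232), sensors of double-stranded RNA (11 of 15 rose, 0.0104 and 0.1) and cytosolic ribosomal proteins (23 of 38 rose, or 24 when adjusted over the list alone, 0.0325 and 0.719). Of these 7 further lists, the RNA sensors differed between the hairpins, and for the other 6 the camera adjusted p between the hairpins was at least 0.102. The ribosomal call was lost without control library 2 or 3 or sh2 library 2. Among the basal markers, TP63, the master factor of squamous cells, changed by -1.28 ± 0.03 and -1.16 ± 0.03, and NGFR by -1.98 ± 0.041 and -1.95 ± 0.04. JAG1, a Notch ligand, changed by -1.86 ± 0.049 and -0.83 ± 0.042. Of the leukocyte markers, CD68 rose with both hairpins, from 78.2 ± 1.98 CPM in control to 124 ± 3.76 with sh1 and 118 ± 8.11 with sh2. CD74 fell with sh1 and rose with sh2, with 83.7 ± 1.54, 75.1 ± 4 and 128 ± 5.83 CPM in control, sh1 and sh2. CORO1A rose with sh2 alone, with 6.87 ± 0.216, 6.76 ± 0.713 and 15.1 ± 0.226 CPM, and CSF1R, which lies below the limit of 1 CPM for named genes, rose with both hairpins, with 0.351 ± 0.138, 1.36 ± 0.234 and 0.944 ± 0.0134 CPM in that order.

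Between the hairpins, the preset correlation also called the stress response list (18 of 29 lower with sh1, camera adjusted p = 0.0357, and 0.235 with an estimated correlation), immediate early genes (21 of 30 lower, 0.00614 and 0.279), interferon-stimulated genes (24 of 32 lower, 0.00268 and 0.132), squamous differentiation (21 of 35 lower, 0.0264 and 0.255), mesenchymal and matrix genes (12 of 24 higher, 0.0294 and 0.261) and apoptosis regulators (16 of 30 lower, 0.0365 and 0.329). The apoptosis call was lost without sh2 library 2, and the squamous and mesenchymal calls without the filter on low counts.

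Against control, camera called neither hairpin for p53 targets (adjusted p = 0.833 for sh1 and 0.247 for sh2), squamous differentiation (0.499 and 0.603), epithelial junctions (0.274 and 0.961), mesenchymal and matrix genes (0.0801 and 0.703), metalloproteinases and the plasminogen system (0.542 and 0.803), Wnt targets (0.833 and 0.179), fatty acid synthesis (0.09 and 0.27), ribosome biogenesis and MYC targets (0.154 and 0.34), apoptosis regulators (0.163 and 0.582), autophagy and lysosome (0.175 and 0.0744), chromatin regulators (0.349 and 0.499), genes altered in esophageal squamous carcinoma (0.603 and 0.501), RNA interference machinery (0.232 and 0.314), metallothioneins and metal response (0.232 and 0.0801) and endothelial markers (0.196 and 0.482). Median and mean differed in sign for Wnt targets with sh1 (-0.08 and 0.14), apoptosis regulators with sh2 (-0.04 and 0.02) and the carcinoma genes with sh1 (0.07 and -0.09), and camera pointed up for epithelial junctions with sh2, where the median was -0.01 and the mean -0.08. Single members of these lists still changed: MYC by -0.94 ± 0.03 and -0.96 ± 0.029, the tight junction gene CLDN1 by -1.27 ± 0.042 and -2.22 ± 0.047, the integrin gene ITGA5 by 1.62 ± 0.041 and 1.57 ± 0.041, MMP7 by 0.95 ± 0.078 and 2.26 ± 0.064, and the BH3-only gene BMF by 1.98 ± 0.059 and 1.51 ± 0.062. Fibroblast and erythroid markers had 4 and 1 tested members and were not tested as lists.

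YAP targets were lower with both hairpins, and so were immediate early genes, whose call with sh2 was lost (adjusted p = 0.0556 with an estimated correlation in camera). Cultures that were denser or growing more slowly in the hairpin groups could lower both lists. Slower growth through a smaller share of cycling cells would then lower the cell cycle lists as well. Slower passage through the cycle, or density without slower growth, need not. The G1/S list rose instead with both hairpins (medians 0.69 and 0.6, camera adjusted p = 0.0156 for both with an estimated correlation). This argues against a smaller share of cycling cells in the hairpin groups. It cannot decide on slower passage through the cycle or on density alone, because growth and cycle phase were not measured. The lowest median of both cell cycle lists was 0.31 (G2/M genes with sh1, a call lost at adjusted p = 0.0556 with an estimated correlation in camera). Slower passage through the cycle, density without slower growth, a change in signalling and the state of the 1 control culture stay open as explanations.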
